A study of Mus musculus with 15 samples.

How the data were processed

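RNA from sorted Pcm1-positive nuclei of mouse ventricular muscle was sequenced after removal of ribosomal RNA, with a directional library kit. Pcm1 is a protein of centriolar satellites that marks the nuclei of cardiomyocytes. The 15 libraries carry labels of genotype (Pgr knockout or wild type) and sex, which give 4 knockout female, 4 knockout male, 3 wild-type female and 4 wild-type male libraries. Pgr encodes the progesterone receptor, a steroid-activated transcription factor. The tissue label holds the numbers 3 and 6 without a unit, and what they stand for is not given in the sources used here. No label says that the replicates are separate animals, litters or preparation days, so each p-value measures only the spread between these samples.

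The authors aligned the reads with STAR 2.5.3a and counted them with featureCounts 1.5.0 on GRCm38 (mm10). The deposited tables hold raw counts per gene for each library, without normalisation. The larger table has 55536 genes, and the length of each gene equals its end minus its start plus 1 in 100% of them, so counts cover whole gene bodies, introns included. The smaller table holds 16610 of these genes with identical counts, and keeps the genes with a mean of at least 10 counts over the 15 libraries. The name of the table holds abbreviations that read as paired ends, reversed strand and a quality of 30, which the sources used here do not explain. Everything below starts from the larger table.

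Counts were analysed in R 4.3.3. Genes were kept by filterByExpr in edgeR 4.0.16, which left 17455 tested genes, and libraries were scaled by the trimmed mean of M values (TMM). A quasi-likelihood model with 1 mean per group was fitted to all 15 libraries (glmQLFit with robust dispersion, 11 residual degrees of freedom), because each group has only 3 or 4 libraries. The 6 comparisons are the label knockout minus wild type in females, the same in males, the difference between these effects, their average, and female minus male within each genotype label. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over the tested genes. Standard errors of log2 fold changes were taken from the estimate and its F statistic. Normalised counts are CPM on TMM library sizes, given as mean ± SD. Measures of single genes or scores were compared by two-sided exact permutation tests, with Benjamini-Hochberg adjustment over the 4 pairs of groups compared for each measure. These tests do not use replicate numbers as pairs. For genes with few reads in a group, the ratio of pooled reads has a 95% interval from the exact Poisson test. Where a group has 0 reads, the ratio is taken against 3 counts over the whole group and is a lower bound.

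Total counts ranged from 24.4 to 139.4 M per library, with a median of 49.9 M. A floor of 3 counts in a library equals 0.0219 to 0.117 CPM. Intervals, floors and the binomial and chi-square p-values of single libraries cover counting error only, since reads without molecular identifiers are not independent molecules.

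Before the data were examined, the groups, the comparisons, the model, 38 gene lists, the rule for named genes and the first set of alternatives were written down. The lists cover energy metabolism, contractile and stress genes, signalling, steroid receptors and their targets, RNA classes, markers of other cell types, sex-linked genes and neighbours of Pgr, and 815 list members were tested. Lists with at least 5 tested members were tested by camera on the edgeR fit with a preset correlation of 0.01, two-sided, adjusted over the 38 lists of a comparison. Beside it stand camera with a correlation estimated for each list and fry, whose p-value asks whether the genes of a list move on balance in 1 direction without comparing them with other genes. The rule for named genes takes up to 12 higher and 12 lower called genes per comparison with the smallest p, leaving out predicted names, or every called gene where 5 or fewer pass. It adds Pgr, Pcm1, the sex-linked genes Xist, Ddx3y, Kdm5d, Uty and Eif2s3y, and up to 4 members of each list with the smallest unadjusted p.

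Calls among genes within 20 Mb of Pgr were compared with those elsewhere by a two-sided Fisher exact test. Agreement between effects was measured by correlations across genes, which are not independent replicates, so no p is given. Replicate numbers were checked as possible pairs by correlating the libraries' deviations from their group means. Same-numbered libraries had correlations of 0.169 to 0.699 between the male groups and -0.41 to 0.708 between the female groups. Between the sexes they were 0.503 to 0.829 under the knockout label and 0.179 to 0.842 under the wild-type label. All but the female groups counted as paired. The closest partner often bore another number. The wild-type female replicates 2 and 3 were closest to the wild-type male replicates 3 and 4. The knockout female replicates 1 and 4 were closest to the knockout male replicates 2 and 3. Between the labels, replicate 2 of the knockout females and of the knockout males was closest to the wild-type replicate 1 of its sex. After a term for the content of other cell types, described next, the correlations of same-numbered libraries lay between -0.355 and 0.355, so pairing beyond that content is not shown.

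The libraries fell into 6 with high and 9 with low levels of 97 marker genes of endothelial cells, fibroblasts, leukocytes and mural cells, separated at the widest gap of their mean log2 CPM (prior count 2). This split was seen in the data and was used only for alternatives. The alternatives planned beforehand were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom (limma 3.58.1) with quality weights, no or a stricter low-count filter, the smaller table, a replicate block, a fit of only the compared groups, 1 surrogate variable (sva 3.50.0), leaving out mitochondrial and the 10 most abundant genes, an adjusted p threshold of 0.10, other windows around Pgr and leaving out each library in turn. Added after the data were seen were a term for the split or for the marker score, the term in DESeq2, the libraries of either kind alone, and leaving out the 3 libraries with reads of the other sex.

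The procedure was tested on simulated data in which 200 of 17455 genes were changed 1.5-, 2- or 4-fold in counts drawn with the fitted spread. Of the genes changed 4-fold, edgeR recovered 69.7% in the female comparison, 60.6% in the male comparison and 43.9% in the difference between them. At 2-fold it recovered 19.4%, 31.3% and 2.99%. False calls made up 3.08% of its calls in the female comparison, against 25.7% for DESeq2 and 3.17% for limma-voom. A simulated 1.3-fold rise of the 21 clock genes in males was called by camera (adjusted p = 0.00157). Genes were drawn independently of each other, so the simulation does not show how often lists of correlated genes are called by chance. Nor did it hold the split by marker levels or the reads of the other sex, so its recovered shares may not carry over. In the real data edgeR did not call Pgr in females (adjusted p = 0.315). It did not call Xist between sexes under the wild-type label either (adjusted p = 0.396).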

Results

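The series asks how the progesterone receptor controls heart maturation in a sex-specific way. Nuclear RNA of ventricular cardiomyocytes was measured by RNA-seq in 15 mouse libraries, 4 labelled Pgr knockout female, 4 labelled knockout male, 3 labelled wild-type female and 4 labelled wild-type male. Total counts were 47.5, 55.4, 42.3 and 49.9 M in the female libraries labelled knockout and 25.0, 72.1, 65.6 and 139.4 M in the male ones. They were 24.4, 28.6 and 51.4 M in the female libraries labelled wild type and 61.5, 43.4, 49.2 and 91.7 M in the male ones. Positions are those of GRCm38, levels are normalised counts (CPM, mean ± SD), and fold changes are log2 values with their standard error (SE) from edgeR.

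Pgr reads ran against the genotype labels in all 15 libraries. Pgr, the gene of the progesterone receptor (chromosome 9, 8899833 to 8968611, plus strand), stood at 10.9 ± 1.67 CPM in the female libraries labelled knockout (n = 4) and at 0.128 ± 0.134 CPM in those labelled wild type (n = 3). In males it stood at 6.58 ± 0.465 CPM under the knockout label (n = 4) and at 0.0640 ± 0.0802 CPM under the wild-type label (n = 4). Single libraries labelled knockout held 8.69, 11.9, 12.5 and 10.6 CPM in females and 6.32, 6.10, 6.75 and 7.15 CPM in males. Of the 7 libraries labelled wild type, 3 had 0 Pgr reads, and the others had 3 and 7 reads in females and 6 and 7 reads in males. The ratio of pooled reads was 114 in females (95% interval 62.1 to 239, 2143 against 10 reads) and 126 in males (73.6 to 237, 2047 against 13 reads). The difference between the labels had an exact permutation p = 0.0286 in each sex, the smallest that the 35 arrangements in females or the 70 in males can give (adjusted p = 0.0381). Every direction between genotypes is therefore given by label alone, and a value called higher in the libraries labelled knockout is higher where Pgr reads are present.

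Pcm1, which encodes the protein used for sorting, was at 195 ± 26.0, 166 ± 10.6, 183 ± 48.6 and 184 ± 41.2 CPM in knockout female, knockout male, wild-type female and wild-type male libraries by label (n = 4, 4, 3 and 4). Its exact permutation p was 0.714 between genotype labels in females and 0.429 in males. The sex-linked genes followed the sex labels. Xist, the RNA that silences an X chromosome, was at 1560 ± 305 CPM (n = 4) and 1533 ± 399 CPM (n = 3) in the female libraries labelled knockout and wild type, and at 0.631 ± 0.137 CPM in the male libraries labelled knockout (n = 4). In the male libraries labelled wild type the mean of 14.6 ± 26.4 CPM (n = 4) rests on replicate 2 with 54.2 CPM, while the others lay between 0.335 and 2.64 CPM. Those 54.2 CPM are 3.72% of the mean over the female libraries, replicate 2 of both labels left out. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y reached 3.03% to 3.16% of the male mean in the knockout female replicate 2 and 2.38% to 3.40% in the wild-type female replicate 2, and at most 0.424% in the other 5 female libraries.

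**Figure D1:**
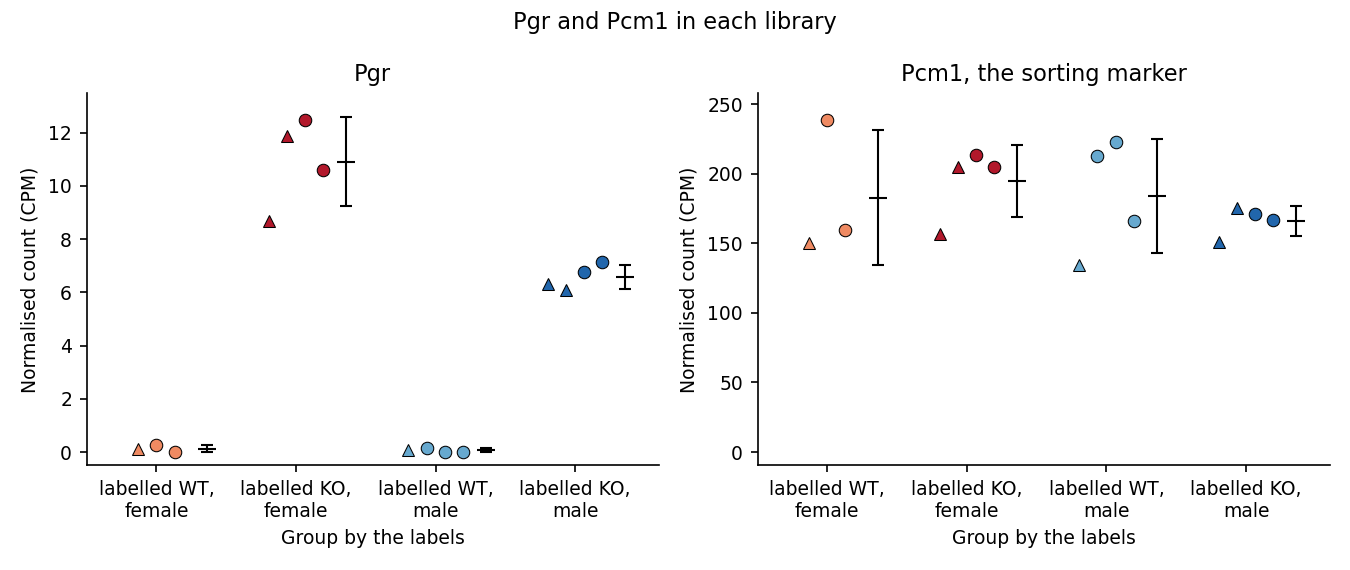
Normalised counts (CPM) of Pgr (left) and Pcm1 (right) in each library by label, with triangles for the 6 libraries with high levels of markers of other cell types, circles for the other 9, and bars for the group mean ± SD. All 8 libraries labelled knockout lie between 6.10 and 12.5 CPM of Pgr, and the 7 labelled wild type between 0 and 0.267 CPM.

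**Figure D2:**
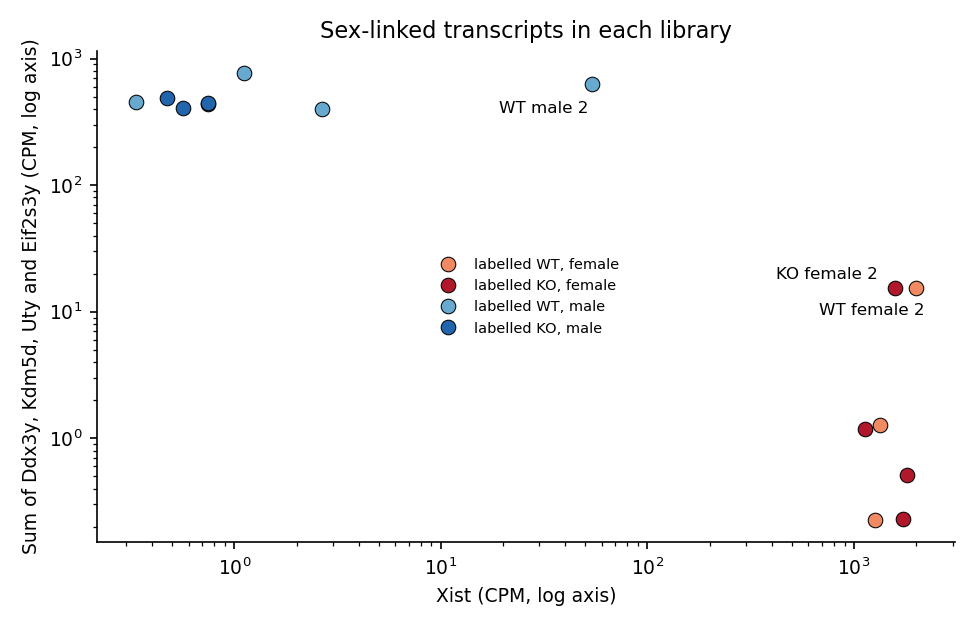
Xist against the sum of 4 Y-linked genes in each library (both axes logarithmic, CPM), coloured by label. The 3 named libraries, all replicate 2, carry transcripts of the other sex at a few percent of its level, while every library lies on the side of its sex label.

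Markers of other cardiac cell types split the libraries in a way the labels do not describe. In 6 libraries (replicates 1 and 2 of both groups labelled knockout and replicate 1 of both groups labelled wild type) Pecam1, an endothelial adhesion molecule, was at 37.0 to 79.5 CPM, against 2.62 to 8.06 CPM in the other 9. Dcn, a matrix proteoglycan of fibroblasts, was at 81.3 to 328 CPM against 10.8 to 37.6 CPM, and Rgs5, a pericyte gene, at 29.1 to 80.9 CPM against 6.22 to 13.4 CPM. The leukocyte gene Ptprc (4.41 to 13.7 CPM against 0.637 to 4.74 CPM) and the cardiomyocyte genes Myh6 (2963 to 5711 CPM against 3097 to 6288 CPM) and Ttn (23125 to 39930 CPM against 32734 to 41846 CPM) overlapped between the libraries. The first principal component held 61.8% of the variance and separated the same 6 libraries. By label, 2 of 4 knockout female, 2 of 4 knockout male, 1 of 3 wild-type female and 1 of 4 wild-type male libraries were among the 6.

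**Figure D3:**
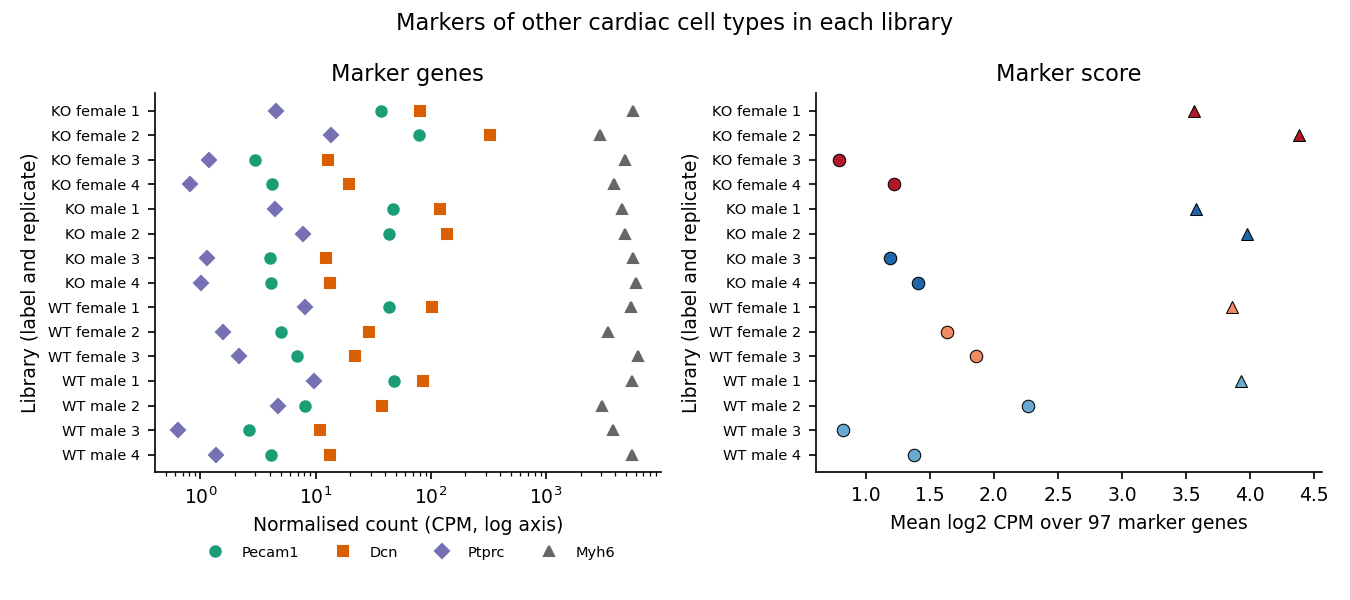
Left, CPM (log axis) of Pecam1, Dcn, Ptprc and the cardiomyocyte gene Myh6 in each library. Right, the mean log2 CPM of 97 marker genes, where the 6 libraries drawn as triangles lie at 3.56 or higher and the other 9 at 2.27 or lower.

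In females, the comparison of the genotype labels (n = 4 and 3) was led by Pgr, at a log2 fold change of 6.61 ± 1.0 (SE). Of 2 non-coding genes beside it, low in the libraries labelled knockout but above the others, Gm32014 ranked 2nd by p and Gm16485 5th, after Gm12092 and Gm19324. Gm32014 (chromosome 9, 8644073 to 8740988) had 50 reads against 1, a pooled ratio of 26.7 (95% interval 4.58 to 1080), and Gm16485 (chromosome 9, 8971791 to 8975773) had 59 against 2, a ratio of 15.8 (4.17 to 133). edgeR called 0 genes, with an adjusted p = 0.315 for Pgr, and 303 genes had an unadjusted p under 0.05 where 873 would be expected without differences. The common dispersion of the fit was 0.163, and 0.0434 with a term for the marker levels, so that split adds to the spread. A count of 0 therefore does not show that no gene differs. With 1 surrogate variable edgeR called Pgr (adjusted p = 0.000206). DESeq2 called 3 genes (Pgr, and Gm12092 and Gm19324, named here after their values were seen) and limma-voom called 1 (Pgr).

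Of 10 lists called in females, 8 were lower in the libraries labelled knockout. Of the adult sarcomere list 21 of 25 members had lower values (median -0.19, adjusted p = 2.15e-06; adjusted p = 0.683 with an estimated correlation). Among them were Myot, a Z-disc protein, at -0.83 ± 0.33, and the thin-filament genes Lmod2 at -0.28 ± 0.13 and Tnnc1 at -0.35 ± 0.21. Nuclear genes of oxidative phosphorylation were lower in 41 of 43 (median -0.13, adjusted p = 2.15e-06; adjusted p = 0.857 with an estimated correlation). Cases are the complex IV subunit Cox5b at -0.28 ± 0.16 and the complex III subunit Uqcrq at -0.29 ± 0.18. Glycolysis was lower in 20 of 23 (adjusted p = 0.0012; adjusted p = 0.81 with an estimated correlation), and its members include the enzymes Pfkl at -0.33 ± 0.17 and Pgam2 at -0.36 ± 0.19. The tricarboxylic acid cycle was lower in 21 of 22 (adjusted p = 0.0142; adjusted p = 0.969 with an estimated correlation). Without the 3 libraries with reads of the other sex it took the opposite direction (adjusted p = 0.743). Members include the dehydrogenase genes Sdhb at -0.24 ± 0.18 and Idh2 at -0.19 ± 0.15.

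Fetal and stress-induced cardiac genes were lower in 14 of 22 (adjusted p = 0.0051; adjusted p = 0.593 with an estimated correlation). They include the stress cytokine Gdf15 at -1.17 ± 0.45, the natriuretic peptide Nppb at -0.80 ± 0.46 and the slow myosin Myh7 at -0.65 ± 0.43. Heat shock genes were lower in 16 of 17 (adjusted p = 0.0188; adjusted p = 0.969 with an estimated correlation). Examples are the chaperones Dnajb4 at -0.30 ± 0.25 and Hsph1 at -0.78 ± 0.88. Clock genes were lower in 15 of 21 (adjusted p = 0.0332; adjusted p = 0.844 with an estimated correlation). In the libraries with low marker levels alone they took the opposite direction (adjusted p = 0.98). Examples are the repressors Cry1 at -0.48 ± 0.33 and Per2 at -0.72 ± 0.55. Abundant nuclear non-coding RNAs were lower in 10 of 15 (adjusted p = 0.0332; adjusted p = 0.593 with an estimated correlation). The smallest p was that of Rn7sk at -0.80 ± 0.42. Of 2 higher lists, 1 was interferon-stimulated genes (24 of 27 higher, adjusted p = 0.0392; adjusted p = 0.969 with an estimated correlation), such as Rtp4 at 0.52 ± 0.17. This list took the opposite direction with a term for the marker levels (adjusted p = 0.973), in the libraries with low marker levels alone (0.864) and without the 3 libraries with reads of the other sex (0.205), and was not called without the wild-type female replicate 2 (0.944) or 3 (0.525) or the knockout female replicate 1 (0.426) or 2 (0.81). The other was steroid receptors (15 of 19 higher, adjusted p = 0.0104; adjusted p = 0.593 with an estimated correlation), which include Pgr itself. Adjusted over the list alone, Pgr passed (adjusted p = 0.00034) and 0 members of the other lists called in females did. Of the 10 list calls, 1, that of the sarcomere, held in each of the 15 fits without 1 library but not in the libraries with low marker levels alone (adjusted p = 0.0525), and without the wild-type female replicate 2 the adjusted p of oxidative phosphorylation was 0.414. In these groups 2 of 4 and 1 of 3 libraries carried high marker levels, and the fibroblast list, higher in 31 of 31 members, missed the threshold (adjusted p = 0.145). In a fit with the replicate block the fibroblast (adjusted p = 0.000653) and endothelial lists (0.027) were called as higher, and the clock (0.073) and abundant non-coding RNA lists (0.0717) were not called.

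In males, Pgr and Gm32014 rose in the libraries labelled knockout (n = 4 against 4). Pgr had a log2 fold change of 6.77 ± 0.884 (SE, adjusted p = 0.04995) and Gm32014 one of 4.24 ± 0.596 (adjusted p = 0.04995), with 147 against 5 reads, a pooled ratio of 23.6 (95% interval 9.87 to 73.6). Gm16485 had 64 reads against 0, at least 17.1-fold higher with a floor of 3 counts over the group, and an edgeR adjusted p = 0.114. Among 33 tested neighbours of Pgr, Pdgfd, a growth factor of the platelet-derived family, at -1.28 ± 0.284 and Cep126, a gene of centrosomes and cilia, at -0.82 ± 0.209 passed when adjusted over the list alone (adjusted p = 0.0169 and 0.0256), and neither over all genes. Both adjusted p-values of the called genes lie just under the threshold, and 1 or 0 genes were called in each of the 15 fits without 1 library, 1 without the knockout female replicate 4 or the wild-type female replicate 3 and 0 without any of the others. With the replicate block both genes had an adjusted p = 0.0123, and with 1 surrogate variable Pgr had 2.82e-05 and Gm32014 0.00216. DESeq2 called 4 genes, Pgr, Gm32014, Gm16485 and Pdgfd. With limma-voom 2 genes were called, Pgr and Gm16485 but not Gm32014. Without a low-count filter edgeR called 2 genes, Gm32014 and Gm16485 but not Pgr.

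In males, the 12 mitochondrially encoded transcripts were all higher in the libraries labelled knockout (median 0.58, adjusted p = 1.43e-06; adjusted p = 0.759 with an estimated correlation). Mitochondrial reads made up 0.796% and 1.12% of the counts in the knockout male replicates 1 and 2, which carry high marker levels, 0.41% and 0.404% in replicates 3 and 4, and 0.391% to 0.506% in the males labelled wild type. The list was not called without the knockout male replicate 2 (adjusted p = 0.0619) or in the libraries with low marker levels alone (0.315). Examples are the ribosomal RNA mt-Rnr1 at 0.94 ± 0.41 and mt-Nd4 at 0.80 ± 0.39. The RNA came from sorted nuclei after removal of ribosomal RNA. What set the level of mitochondrially encoded transcripts was not tested in any comparison. The sarcomere list was higher in 20 of 25 (adjusted p = 0.000853; adjusted p = 0.921 with an estimated correlation). Examples are the cardiac actin Actc1 at 0.37 ± 0.17 and the light chain Myl3 at 0.30 ± 0.18. Fetal and stress-induced genes were higher in 17 of 22 (adjusted p = 0.00198; adjusted p = 0.759 with an estimated correlation). One is the skeletal actin Acta1 at 0.73 ± 0.35. Ribosomal protein genes (40 of 44 higher, adjusted p = 1.43e-06; adjusted p = 0.921 with an estimated correlation) included Rps2 at 0.48 ± 0.24. Immediate early genes (20 of 26 higher, adjusted p = 0.00427; adjusted p = 0.921 with an estimated correlation) included the phosphatase Dusp5 at 0.49 ± 0.19 and the growth inhibitor Btg2 at 0.69 ± 0.33. Oxidative phosphorylation was higher in 28 of 43 (adjusted p = 0.0196; adjusted p = 0.921 with an estimated correlation). One member is Cox7a1 at 0.56 ± 0.24. This call was lost with the replicate block (adjusted p = 0.0748).

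Lower in the male libraries labelled knockout were clock genes in 16 of 21 (median -0.42, adjusted p = 1.2e-05; adjusted p = 0.677 with an estimated correlation). They include the nuclear receptor Nr1d2 at -0.42 ± 0.17, the repressor Ciart at -1.86 ± 0.78 and Cry1 at -0.70 ± 0.31. Fatty acid oxidation was lower in 23 of 28 (adjusted p = 0.000798; adjusted p = 0.921 with an estimated correlation). Examples are the enzymes Decr1 at -0.46 ± 0.27 and Acaa2 at -0.37 ± 0.23. Neighbours of Pgr were lower in 22 of 33 (adjusted p = 0.000182; adjusted p = 0.759 with an estimated correlation). Marker lists of 5 kinds were higher, beside 2 of 4 libraries with high marker levels under the knockout label and 1 of 4 under the other. They were fibroblast (31 of 31 higher, adjusted p = 0.0034), endothelial (24 of 25, 0.00924), mural cell (15 of 18, 0.022), erythroid (6 of 8, 0.0227) and epicardial markers (14 of 15, 0.0115), each with an adjusted p = 0.921 with an estimated correlation. With a term for that split, which was defined from genes of these lists, the fibroblast and endothelial lists turned lower (adjusted p = 0.0227 and 0.0265, and 0.000552 and 0.00199 in DESeq2). Without the knockout male replicate 2, the adjusted p of the fibroblast list was 0.93 in the opposite direction, and 2 of the 14 list calls in males, those of the clock and of the neighbours of Pgr, held in each of the 15 fits. In the libraries with high marker levels alone, with only 1 male library labelled wild type, the neighbours of Pgr took the opposite direction.

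The difference between the sexes in the effect of the genotype label, the question in the series title, gave 0 called genes by edgeR, with 435 genes at an unadjusted p under 0.05, and 1 gene each by DESeq2 and limma-voom. That gene was Capn3, a muscle protease, chosen here after its values were seen, at 1.89 ± 0.987 CPM (knockout label, n = 4) against 4.21 ± 0.83 CPM (wild-type label, n = 3) in females and 5.48 ± 0.820 against 2.5 ± 0.541 CPM (n = 4 and 4) in males. Its edgeR difference was -2.29 ± 0.443 (adjusted p = 1). Across 17455 genes the effects in females and males had a Pearson correlation of 0.07 and a Spearman correlation of -0.08, and 42.6% of genes had the same sign. The Spearman correlation lay between -0.333 without the wild-type female replicate 2 and 0.153 without the wild-type female replicate 1.

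By list, the sex difference in the label's effect was called in 11 of 38. In 7 lists the effect was lower in females than in males: sarcomere (20 of 25 lower, adjusted p = 2.26e-07), oxidative phosphorylation (38 of 43, 3.64e-06), mitochondrially encoded transcripts (12 of 12, 6.23e-06), fetal and stress-induced genes (19 of 22, 6.35e-05), ribosomal proteins (40 of 44, 6.35e-05), glycolysis (19 of 23, 0.017) and immediate early genes (17 of 26, 0.017). With an estimated correlation none of these 7 was called, nor any of the 4 lists that follow (adjusted p = 0.564 to 0.929 with an estimated correlation). Examples of the 7 are Actc1 at -0.56 ± 0.25, Tnnc1 at -0.61 ± 0.28, Gdf15 at -1.62 ± 0.60 and Uqcrq at -0.60 ± 0.25. Fatty acid oxidation (22 of 28 higher, adjusted p = 0.035), glucocorticoid-responsive genes (18 of 21, 0.0491), genes escaping X inactivation (10 of 14, 0.044) and neighbours of Pgr (30 of 33, 0.00282) had a higher effect in females, for example the hormone-induced Klf9 at 0.44 ± 0.16. Calls of the sarcomere, the mitochondrially encoded and the fetal lists held in each of the 15 fits without 1 library, while the fetal list was not called with limma-voom (adjusted p = 0.0826). The libraries with high marker levels alone include 1 library labelled wild type in each sex, too few to weigh these calls. Without the wild-type female replicate 1, fatty acid oxidation had an adjusted p = 0.808 in the opposite direction. Under the replicate block fatty acid oxidation (adjusted p = 0.181), glucocorticoid-responsive genes (0.0556) and immediate early genes (0.0688) were not called, and the tricarboxylic acid cycle (0.0269), steroid receptors (0.0471) and interferon-stimulated genes (0.0139) were.

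**Figure D4:**
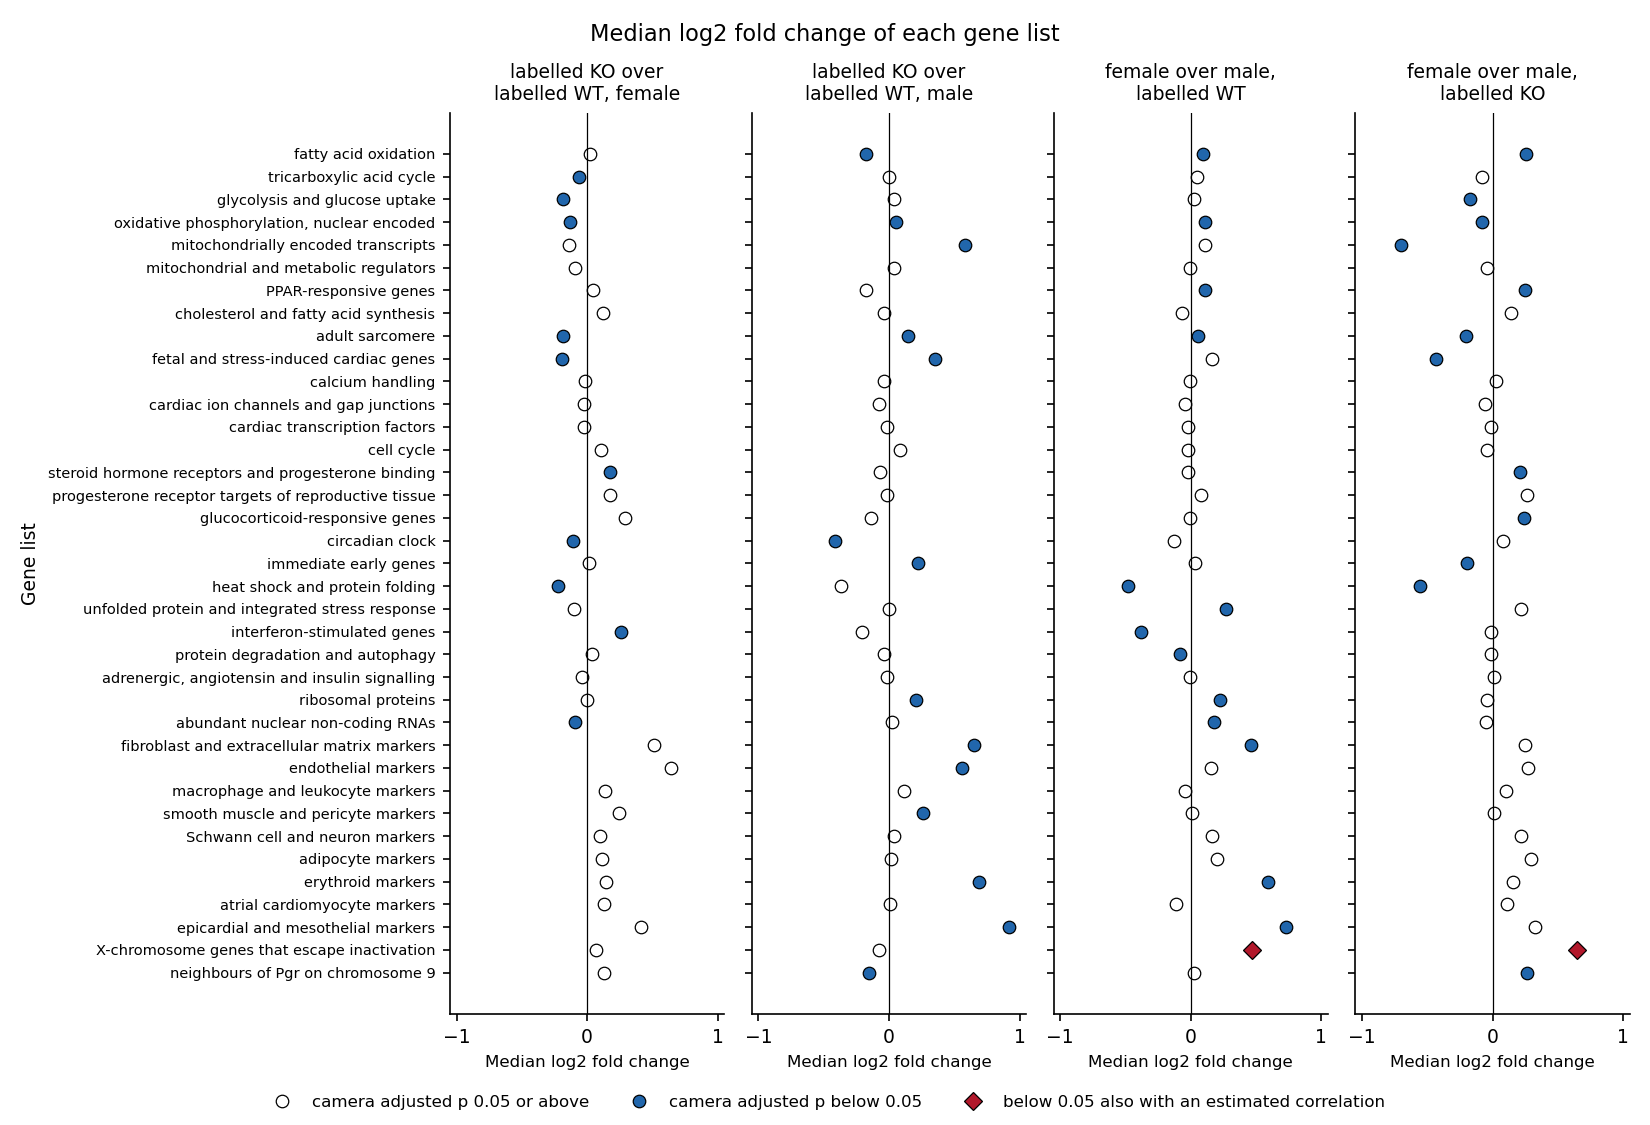
Median log2 fold change of each gene list in 4 comparisons, the genotype labels in females and males and the sexes within each genotype label, with filled points for a camera adjusted p below 0.05. Red diamonds mark the lists also called with an estimated correlation, which among the lists drawn is the X-escape list in both sex comparisons; the Y list lies off the scale and is left out.

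Averaged over sexes, edgeR called 3 genes as higher in the libraries labelled knockout and 0 as lower, all 3 within 0.2 Mb of Pgr. They were Pgr (6.69 ± 0.681 SE, adjusted p = 0.00412), Gm32014 (4.38 ± 0.506, adjusted p = 0.00528), which ends 158.8 kb before Pgr, and Gm16485 (5.12 ± 0.607, adjusted p = 0.0261), which starts 3.18 kb after it. These fitted values depend on the prior count where groups have few reads, and the read counts are given above by sex. Within 20 Mb, Pgr included, 3 of 164 tested genes were called, against 0 of 17291 elsewhere (Fisher exact p = 8.14e-07), and 14 of the 164 (8.54%) had an unadjusted p under 0.05 against 1.22% elsewhere. With Pgr left out these were 2 of 163 (Fisher exact p = 8.67e-05) and 13 of 163 (7.98%). Of these 13 genes, 5 lie in a repeat array of 6 genes at the start of chromosome 9. Among the neighbours adjusted over the list alone, Pdgfd (-1.04 ± 0.206) and Cep126 (-0.76 ± 0.153) fell (adjusted p = 0.0034 each), from 122 ± 18.2 to 50.1 ± 13.7 CPM and from 26.9 ± 3.57 to 15.2 ± 2.27 CPM in males (n = 4 and 4). In females Pdgfd stood at 96.6 ± 23.5 and 55.5 ± 25.1 CPM and Cep126 at 22.98 ± 6.48 and 14.1 ± 3.65 CPM under the wild-type and knockout labels (n = 3 and 4), with overlapping libraries for both. With the replicate block Pgr, Gm32014 and Cep126 (-0.78, adjusted p = 0.0209) were the 3 called genes. Without the 3 libraries with reads of the other sex, 1 gene was called. DESeq2 called 7 genes, of which 4, Gm19324 and Samd5 named after their values were seen, were lower. These were Gm19324 (adjusted p = 4.81e-05), Pdgfd (0.000867) and Cep126 (0.00584) on chromosome 9 and Samd5 (0.0254) on chromosome 10. With limma-voom Pdgfd was called as lower too (adjusted p = 0.00814).

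**Figure D5:**
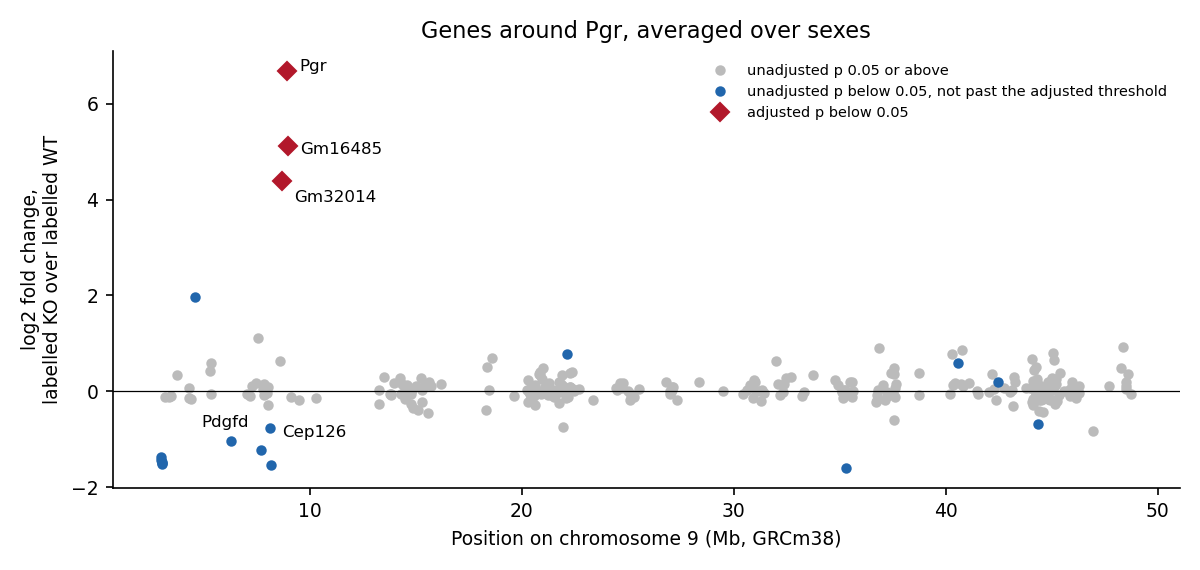
Log2 fold change (knockout over wild type by label, averaged over sexes) of the tested genes within 40 Mb of Pgr against their position on chromosome 9 (Mb, GRCm38). Red diamonds are the 3 called genes, blue points have an unadjusted p below 0.05 only, and grey points have neither.

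Clock genes were the list with the smallest p averaged over sexes: 17 of 21 were lower in the libraries labelled knockout (median -0.17, adjusted p = 3.71e-08; adjusted p = 0.194 with an estimated correlation). Examples are Cry1 at -0.59 ± 0.23, the repressor Bhlhe41 at -0.33 ± 0.14, Per2 at -0.85 ± 0.38 and Ciart at -1.17 ± 0.56, and 0 of the 21 passed when adjusted over the list alone. The call held in each of the 15 fits without 1 library and was lost in the libraries with low marker levels alone (adjusted p = 0.0733). Lower too were fatty acid oxidation (25 of 28, adjusted p = 0.0222), glycolysis (17 of 23, 0.0415) and heat shock genes (14 of 17, 0.0173), each with an adjusted p = 0.914 with an estimated correlation. Higher were fibroblast (31 of 31, adjusted p = 0.000357), endothelial (25 of 25, 0.00517) and epicardial markers (0.019) and ribosomal proteins (0.019), also at 0.914 with an estimated correlation. The marker lists stand beside 4 of 8 libraries with high marker levels under the knockout label and 2 of 7 under the other. With a term for that split, which was defined from genes of these lists, the fibroblast and endothelial lists turned lower (adjusted p = 5.112e-05 and 2.425e-07), and without the knockout female replicate 2 they were not called (adjusted p = 0.923 and 0.967). Other lists turned to the opposite direction too: heat shock genes without the wild-type male replicate 3 (adjusted p = 0.049), ribosomal proteins without the knockout female replicate 2 (0.786) and in the libraries with low marker levels alone (0.00113), and fatty acid oxidation with the term for the split (0.935). Fatty acid oxidation also turned in the libraries with high marker levels alone, with 1 library labelled wild type in each sex. A further 6 lists were called with the replicate block, the tricarboxylic acid cycle (adjusted p = 0.00761), oxidative phosphorylation (0.00524) and mitochondrial and metabolic regulators (0.0333) as lower, and interferon-stimulated genes (0.0168), mural cell (0.0333) and erythroid markers (0.0108) as higher.

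Between the sexes among libraries labelled wild type (3 female, 4 male), which asks for sex differences under that label, edgeR called 0 genes, with 364 at an unadjusted p under 0.05, while DESeq2 called 14 and limma-voom 10. As a list, Y-linked genes were lower in females (6 of 6, adjusted p = 6.87e-40; adjusted p = 0.000755 with an estimated correlation), and adjusted over the list alone 6 of 6 fell, such as the ubiquitin peptidase Usp9y at -4.67 ± 0.857 and the demethylase Kdm5d at -7.02 ± 1.36, the latter at -9.87 without the 3 libraries with reads of the other sex. Genes that escape X inactivation were higher in females (13 of 14, adjusted p = 1.56e-25; adjusted p = 0.00119 with an estimated correlation), and 9 of 14 rose when adjusted over the list alone, such as Kdm5c at 0.62 ± 0.11, Ftx at 0.53 ± 0.14 and Pbdc1 at 0.59 ± 0.16. Gm29650, a Y-linked non-coding gene (chromosome Y, 1048393 to 1049134), had 177 reads in males and 0 in females, at least 25.5-fold lower with the floor over the group (edgeR adjusted p = 0.143). The calcium pump Atp2b2 was at 4.43 ± 1.45 against 15.8 ± 4.77 CPM (-1.83 ± 0.309, adjusted p = 0.308). With the replicate block it was the 1 called gene (adjusted p = 0.0212), and without the wild-type male replicate 2 edgeR called 2 genes. Without the 3 libraries with reads of the other sex edgeR called 6 genes, 1 higher and 5 lower in females.

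Among other lists, ribosomal proteins were higher in the wild-type-labelled females in 43 of 44 members (adjusted p = 2.48e-10; adjusted p = 0.974 with an estimated correlation). Rpl37 was at 0.34 ± 0.17. So were oxidative phosphorylation (42 of 43, adjusted p = 9.23e-06), PPAR-responsive genes (16 of 21, 0.006), fatty acid oxidation (22 of 28, 0.0339), the sarcomere (17 of 25, 0.0135) and the unfolded protein response (15 of 21, 0.006), each with an adjusted p = 0.974 with an estimated correlation. Examples are the peroxisomal enzyme Ech1 at 0.40 ± 0.22, Actc1 at 0.47 ± 0.18 and the secreted stress factor Manf at 0.41 ± 0.21. Fibroblast (30 of 31 higher, adjusted p = 0.0105), erythroid (8 of 8, 0.0241) and epicardial markers (13 of 15, 0.0105) were higher, each at 0.974 with an estimated correlation, beside 1 of 3 female and 1 of 4 male libraries with high marker levels. Lower, and also at 0.974 with an estimated correlation, were heat shock genes (16 of 17, adjusted p = 0.006), such as the chaperone gene Dnaja1 at -1.28 ± 0.70, and interferon-stimulated genes (24 of 27, 0.0128), such as Mx2 at -0.46 ± 0.19. Protein degradation (16 of 23 lower, adjusted p = 0.00918; adjusted p = 0.287 with an estimated correlation) included the ligase Fbxo32 at -0.58 ± 0.21. Abundant non-coding RNAs (11 of 15 higher, adjusted p = 0.00186; adjusted p = 0.109 with an estimated correlation) included Xist at 6.73 ± 1.33, or at 10.16 without the wild-type male replicate 2, which has reads of the other sex. With the replicate block, heat shock (adjusted p = 0.104), fibroblast (0.15) and erythroid lists (0.163) were not called and the tricarboxylic acid cycle was (0.0196). Calls of the ribosomal, Y-linked and X-escape lists held in each of the 15 fits without 1 library. The ribosomal list was not called without the 3 libraries with reads of the other sex (adjusted p = 0.113). In the libraries with high marker levels alone, here 1 female against 1 male, the ribosomal list took the opposite direction. Leaving out the wild-type female replicate 1 turned the fibroblast, erythroid and epicardial lists to the opposite direction (adjusted p = 0.105, 0.851 and 0.723). Leaving out the wild-type male replicate 3 did so for heat shock genes (0.004668) and fatty acid oxidation (0.899), leaving out the wild-type female replicate 2 for fatty acid oxidation (0.668), and leaving out the wild-type male replicate 1 for interferon-stimulated genes (0.316). Oxidative phosphorylation was not called without the wild-type female replicate 2 (0.668), and took the opposite direction without the 3 libraries with reads of the other sex (0.587). It did so too in the libraries with high marker levels alone, 1 female against 1 male.

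Between the sexes among libraries labelled knockout (4 female, 4 male), 1 gene was higher and 3 were lower in females. An unadjusted p under 0.05 was reached by 1112 genes, where 873 would be expected without differences. Xist rose by 11.30 ± 1.61 (adjusted p = 0.0446). Usp9y fell (2418 reads in males and 27 in females, a ratio of 58 with a 95% interval of 39.7 to 88.1, adjusted p = 0.0219). Its log2 fold change of -5.86 became -6.96 without the knockout female replicate 2, which has reads of the other sex. Gm29650 fell (251 reads against 0, at least 54.2-fold with the floor over the group, adjusted p = 0.0185). The autosomal gene Atp2b2 (chromosome 6, 113743831 to 114042613), a calcium pump of the plasma membrane, fell by 2.07 on the log2 scale (SE 0.278, adjusted p = 0.0219), from 22.7 ± 3.68 CPM in males to 5.40 ± 1.76 CPM in females (n = 4 and 4). With the replicate block 13 genes were called in place of 4, all 4 among them and joined by X- and Y-linked genes, Gdf15 and Ankrd63. DESeq2 called 57 and limma-voom 20. The count was 10 without the knockout female replicate 1, 9 without replicate 2, 1 without replicate 3 and 0 without replicate 4. It was 2 without the knockout male replicate 1, 0 without any of replicates 2, 3 or 4, and 2 without the wild-type female replicate 3. Pgr itself was higher in females by 0.73 ± 0.636 (edgeR adjusted p = 0.828), while the CPM values did not overlap (exact permutation p = 0.0286, adjusted p = 0.0381). This permutation ignores the replicate numbers, which counted as pairs in these groups.

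The sex-linked lists were called again, Y-linked genes lower (6 of 6, adjusted p = 1.21e-23; adjusted p = 0.00239 with an estimated correlation) and X-escape genes higher (14 of 14, adjusted p = 6.47e-24; adjusted p = 0.00239 with an estimated correlation), with 5 and 9 members past the threshold when adjusted over the list alone, including Eif2s3x at 0.88 ± 0.15. Fetal and stress-induced genes were lower in the knockout-labelled females in 19 of 22 (median -0.44, adjusted p = 3.07e-05; adjusted p = 0.183 with an estimated correlation). Adjusted over the list alone, Gdf15 (-2.26 ± 0.423), the mechanical stress gene Ankrd1 (-1.04 ± 0.28) and Acta1 (-1.20 ± 0.35) fell. Mitochondrially encoded transcripts (12 of 12 lower, adjusted p = 7.12e-06; adjusted p = 0.572 with an estimated correlation) included mt-Nd4 at -1.01 ± 0.39. The sarcomere (21 of 25 lower, adjusted p = 1.64e-05; adjusted p = 0.572 with an estimated correlation) included Cryab, a small heat shock protein, at -0.83 ± 0.28 and the Z-disc gene Actn2 at -0.51 ± 0.19. Heat shock genes (15 of 17 lower, adjusted p = 0.000212; adjusted p = 0.645 with an estimated correlation) included Hspa8 at -0.67 ± 0.27. Immediate early genes (18 of 26 lower, adjusted p = 0.00111; adjusted p = 0.626 with an estimated correlation) included Nr4a1 at -1.93 ± 0.54 and Btg2 at -1.11 ± 0.33. Glycolysis (18 of 23 lower, adjusted p = 0.02; adjusted p = 0.675 with an estimated correlation) and oxidative phosphorylation (29 of 43 lower, adjusted p = 0.0359; adjusted p = 0.975 with an estimated correlation) were also lower, the latter not with the replicate block (adjusted p = 0.0761).

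Fatty acid oxidation was higher in the knockout-labelled females in 25 of 28 members (median 0.25, adjusted p = 7.12e-06; adjusted p = 0.626 with an estimated correlation). Examples are the thioesterase Acot1 at 1.96 ± 0.66 and Decr1 at 0.76 ± 0.27. PPAR-responsive genes were higher in 19 of 21 (adjusted p = 0.000124; adjusted p = 0.626 with an estimated correlation). Among them was Txnip, an inhibitor of glucose uptake, at 1.47 ± 0.57. Glucocorticoid-responsive genes (19 of 21 higher, adjusted p = 0.02; adjusted p = 0.645 with an estimated correlation), such as Arrdc2 at 0.99 ± 0.37, were higher. So were steroid receptors (16 of 19 higher, adjusted p = 0.0287; adjusted p = 0.426 with an estimated correlation), such as the membrane receptor gene Paqr9 at 0.59 ± 0.22, and neighbours of Pgr (26 of 33 higher, adjusted p = 0.000394; adjusted p = 0.572 with an estimated correlation), such as Ccdc82 at 0.63 ± 0.23. In both sexes 2 of 4 libraries labelled knockout carried high marker levels, and no marker list of another cell type was called. Of the 14 list calls, 8 held in each of the 15 fits without 1 library. Sex effects under the 2 labels had a Pearson correlation of 0.19 and a Spearman correlation of 0.11 across 16876 autosomal genes, with the same sign in 51.8%. The Spearman correlation lay between -0.036 without the wild-type female replicate 2 and 0.272 without the wild-type male replicate 2.

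Without a replicate block, 12 lists were called by camera in none of the 6 comparisons. Their lowest adjusted p-values were 0.102 for cholesterol and fatty acid synthesis, 0.109 for cardiac ion channels, 0.203 for leukocyte markers and for atrial markers, 0.279 for mitochondrial and metabolic regulators, 0.285 for adipocyte markers and 0.302 for progesterone receptor targets of reproductive tissue. They were 0.519 for calcium handling, 0.545 for Schwann cell markers, 0.691 for cardiac transcription factors, 0.7 for the cell cycle and 0.803 for adrenergic, angiotensin and insulin signalling. With the block, the regulators (adjusted p = 0.027) and cholesterol synthesis (0.0351) were called in females. Of the 15 tested receptor targets, 14 were higher in females under the knockout label (median 0.27, adjusted p = 0.302), the lower one being the transcription factor gene Hand2 at -0.71 ± 0.24, and 0 passed in any comparison when adjusted over the list alone. Of all 72 list calls in the 6 comparisons, 4 held with an estimated correlation and 4 lists were called by fry, the Y-linked and X-escape lists in both sex comparisons. In each called list the median, the mean and the test had the same sign.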

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

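The tests of explanations in this part were all chosen after the results they concern had been seen, as were the splits that part replicate pairs, while the other splits of the samples were planned.

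In 10 of 61 groups of 4 libraries, 1 library lay far from the others, where chance gives about 1 in 20 groups, or 3.05 of 61. In the female libraries labelled knockout, replicate 2 had 2.11 CPM of Ddx3y, 2.35 of Kdm5d, 9.30 of Uty and 1.73 of Eif2s3y. Xist was at 54.2 CPM in the wild-type male replicate 2, against 2.64 CPM in the nearest library. Pcm1 was at 156.4 CPM in the knockout female replicate 1, against 204.5 CPM. Gm32014 was at 0.551 CPM in the knockout female replicate 4, Pdgfd at 149 CPM in the wild-type male replicate 4, Cep126 at 11.8 CPM in the knockout male replicate 1 and Gm29650 at 0.691 CPM in the knockout male replicate 2. The Y-linked genes and Xist of these libraries are 1 pattern, weighed next.

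Reads of the other sex were present in 3 libraries, replicate 2 of the knockout female, wild-type female and wild-type male groups by label; how they came in is open, and no biological explanation was tested. Exchanged sex labels are argued against, since the share of the other sex's mean level reached at most 3.72% (Xist, against the female libraries without replicate 2). RNA or reads from 1 source of the other sex may be the cause: by the proportions of the 4 Y-linked genes the closest male library has the same label and number (chi-square p = 0.863 for the knockout female replicate 2 and 0.5845 for the wild-type female replicate 2). The knockout female replicate 2 was told apart from 0 of 8 male libraries and the wild-type female replicate 2 from 5, all 4 labelled knockout among them (chi-square p = 0.000596 to 0.021), where each p covers counting error only. Whether Pgr reads in libraries labelled wild type came from libraries labelled knockout is open: 14 of 23 fell in replicate 2 of the females and males, which hold 20.6% of the total counts (exact binomial p = 2.94e-05, counting error only), but between libraries the exact permutation p was 0.0833, the smallest that 12 arrangements can give.

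Pgr and 2 genes beside it were higher in all libraries labelled knockout. An exchange of the genotype labels could give this, as 15 of 15 libraries lie on the side of the other label. Transcription from the modified locus could as well, since a deletion or insertion can leave or raise transcripts of the gene and its surroundings. Within 1 Mb, 2 genes passed the threshold besides Pgr, both higher. Gm19324 (log2 fold change -1.53, edgeR unadjusted p = 8.46e-05) and Cep126 (-0.764, 0.000206), also within 1 Mb, were lower but did not pass it. An exchange of labels and transcription from the locus cannot be told apart here, because counts over whole gene bodies do not show which part of Pgr was read. Flanking sequence of another strain may add to it: of genes 1 to 20 Mb from Pgr, 4 of 146 (2.74%) had an unadjusted p under 0.05 against 1.22% elsewhere (Fisher exact p = 0.105, odds ratio 2.29, 0.61 to 6.08), a repeat array of 6 genes left out. With the array, of which 5 genes had such a p, the share was 5.92% (Fisher exact p = 0.000131), a value that depends on those 5 genes. Flanking sequence of another strain stays open too, as the interval without the array is wide. Both counts leave out the first 1 Mb, so they do not cover Gm19324 and Cep126.

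The effect of the genotype label differed between the sexes for 11 of 38 gene lists by the test of that difference. It was lower in females for the adult sarcomere (adjusted p = 2.255e-07), oxidative phosphorylation (3.641e-06), mitochondrially encoded transcripts (6.228e-06), fetal and stress-induced genes (6.353e-05), ribosomal proteins (6.353e-05), glycolysis (0.017) and immediate early genes (0.017). It was higher in females for neighbours of Pgr (0.00282), fatty acid oxidation (0.035), X-escape genes (0.044) and glucocorticoid-responsive genes (0.0491). With an estimated correlation 0 of the 11 were called (adjusted p = 0.564 to 0.929), so these calls rest on the preset correlation of 0.01. With the replicate block fatty acid oxidation (0.1808), glucocorticoid-responsive genes (0.05562) and immediate early genes (0.06883) were not called. Of single genes edgeR called 0, a count that any split of the samples reaches (100 of 100), so it says nothing on chance. The highest other split gave 3257 and puts the 4 female libraries with low marker levels together, which points to a structure of the samples.

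Marker lists of other cell types were higher in libraries labelled knockout averaged over sexes. Leaving out the most abundant genes and the mitochondrial genes changed the called genes in 0 of 6 comparisons. The endothelial list stayed called without them (adjusted p = 0.00524, against 0.00517 with them). For that list, this argues against library sizes set by a few abundant genes as the source. An unequal share of libraries with high marker levels, 4 of 8 against 2 of 7, may be the source, but the test does not decide it. With a term for that split the epicardial list lost its call (adjusted p = 0.195). Its median went from 0.69 (quartiles 0.50 and 0.81) to -0.16 (quartiles -0.40 and 0.04). The call was also lost in 8 of 15 fits without 1 library (adjusted p up to 0.9675, without the knockout female replicate 2), so its loss is not particular to that term. Over the alternatives other than leaving out 1 library the adjusted p ranged from 7.53e-06 to 0.924. A different mix of cell types under the knockout label cannot be told apart from that unequal share. The marker score differed by 0.24 with an exact permutation p = 0.74, labels moved within each sex. The sort for Pcm1, a marker of cardiomyocyte nuclei, is meant to remove other cells. Of the lists, 15 of 25 endothelial, 27 of 31 fibroblast, 11 of 18 mural, 6 of 23 leukocyte and 2 of 15 epicardial genes had at least 1 CPM in each library with low marker levels, and which cells these reads come from was not tested.

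Other splits of the samples were counted for each number of called genes. For the average over sexes, 1 of 100 splits (the real one) called 3 genes, and the highest other called 1. Among 100 splits that part the 4 replicate pairs of the males, the highest other called 0. This share is under 0.05 but is the lowest that 100 splits can give, and it was not adjusted over the comparisons. It argues against chance only for the count of these 3 genes, Pgr and 2 genes beside it, and does not exclude chance. In males (2 genes) and between sexes under the knockout label (4 genes) the real split parts all 4 pairs, and the 8 splits that do so are too few for a share under 0.05, with a highest other of 1 and 0. Splits of any kind reached the real count in 1 of 35 in males (highest other 1) and in 2 of 35 under the knockout label (highest other 1943). In females (0 genes, 35 of 35 splits, highest other 0) and between sexes under the wild-type label (0 genes, 35 of 35, highest other 2325) any split reaches the count of 0, so these counts say nothing on chance. The split with 1943 genes parts 0 of the 4 pairs and sets the 4 libraries with high marker levels against the 4 with low ones, and the one with 2325 sets replicate 2 of the females and replicates 2 and 3 of the males against the other 4, so both point to a structure of the samples.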

How the results depend on the processing

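The alternatives with a term or score for marker level, with libraries of 1 marker level alone, and without the 3 libraries with reads of the other sex were chosen after the data were seen. Unless a reason is given, the cause of a change was not tested. In the high-content libraries each group labelled wild type holds 1 library, so what that fit gives carries little weight.

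In females edgeR called 0 genes; DESeq2 called 3, DESeq2 with the content term 4, and limma-voom, 1 surrogate variable, the content term, the content score and the content term without the 3 libraries with other-sex reads 1 each. In males the 2 genes became 0 with RLE or upper-quartile scaling, a mean CPM of at least 1, only the compared groups, the low-content or high-content libraries only, or without the 3 libraries with other-sex reads, the last 4 with fewer samples, and became 4 with DESeq2 and 5 with its content term. For the difference between sexes DESeq2, DESeq2 with the content term and limma-voom each called 1 gene. The average of 3 became 7 with DESeq2, 9 with its content term, and 1 with a mean CPM of at least 1, high-content libraries only, or without the 3 libraries with other-sex reads.

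Between sexes under the wild-type label 0 became 14 with DESeq2, 10 with limma-voom, 20 with DESeq2 and the content term, 6 without the 3 libraries with other-sex reads, 7 so with the content term, and 1 with no low-count filter, the replicate block, 1 surrogate variable, the content term, the content score, or the low- or high-content libraries only. Under the knockout label 4 became 57 with DESeq2, 20 with limma-voom, 78 with DESeq2 and the content term, 13 with the replicate block, 12 with 1 surrogate variable, 11 with the content term, 16 with the content score, 7 without the 3 libraries with other-sex reads and 10 so with the content term. It became 2 with no low-count filter or a mean CPM of at least 1, and 1 with only the compared groups or the low- or high-content libraries only.

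Leaving out each library in turn gave 0 to 1 genes in males, 2 to 4 for the average, 0 to 2 between sexes under the wild-type label and 0 to 10 under the knockout label. The 72 list calls became 56 to 88, the correlation of label effects -0.334 to 0.153 and that of sex effects -0.036 to 0.272. Calls near Pgr, itself included, stayed past the threshold (Fisher exact p = 7.54e-09 to 8.94e-05). The list calls became 4 with the estimated correlation, 4 with fry and 43 with limma-voom, and the correlation of sex effects 0.0174 with the replicate block. Of 2354 values of called lists under alternatives, 1850 kept direction and call, 439 lost the call and 65 reversed. Of 3166 values of named genes, 2891 were within 1 SE or kept their call, 84 moved further, 85 gained and 106 lost a call.

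Lists that reversed did so as follows (adjusted p). With the content term: in females interferon 0.973; in males fibroblast 0.0227, endothelial 0.0265 and epicardial 0.918; averaged, fatty acid oxidation 0.935, fibroblast 5.112e-05, endothelial 2.425e-07 and epicardial 0.195. With the content term in DESeq2: in males fibroblast 0.000552, endothelial 0.00199 and epicardial 0.384; averaged, fibroblast 1.919e-05, endothelial 1.439e-07 and epicardial 0.289. In low-content libraries only: in females clock 0.98 and interferon 0.864; in males fibroblast 0.008145, endothelial 0.131 and epicardial 0.149; averaged, heat shock 0.914, ribosomal 0.001134, fibroblast 7.984e-11, endothelial 7.499e-14 and epicardial 0.0002436. In high-content libraries only: in females oxidative phosphorylation 0.797; in males fatty acid oxidation 0.699, endothelial 0.422, mural 0.425 and neighbours 0.615; for the sex difference glycolysis 0.8845 and ribosomal 0.9002; averaged, fatty acid oxidation 0.002532; under the wild-type label between sexes fatty acid oxidation 0.304, oxidative phosphorylation 0.686, heat shock 0.0507 and ribosomal 0.893. Without the 3 libraries with reads of the other sex: in females tricarboxylic acid cycle 0.743 and interferon 0.205; averaged, fatty acid oxidation 0.636, ribosomal 0.776, fibroblast 0.776, endothelial 0.41 and epicardial 0.924; between sexes oxidative phosphorylation 0.587. Without them and with the content term these were, in that order, 0.91, 0.344, 0.378, 0.8505, 0.003389, 6.379e-08, 0.392 and 0.87. With limma-voom averaged heat shock and endothelial were 0.666.

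Without 1 library, the lists that reversed ranged from 6.75e-08 to 0.93 (fibroblast, males), 3.2e-05 to 0.919 (fatty acid oxidation, sex difference), 1.03e-05 to 0.2365 (heat shock, averaged) and 1.1e-05 to 0.912 (ribosomal, averaged). Between sexes under the wild-type label they ranged from 5.08e-10 to 0.899 (fatty acid oxidation), 4.83e-08 to 0.133 (heat shock), 1.64e-07 to 0.722 (interferon), 1.22e-06 to 0.8615 (fibroblast), 0.00324 to 0.8515 (erythroid) and 1.79e-05 to 0.7545 (epicardial). Depth limits genes with few reads, since 3 counts equal 0.0219 to 0.117 CPM.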

Other observations

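The windows and genes of this part were chosen after their values were seen.

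Averaged over sexes, genes with an unadjusted p under 0.05 were counted in 540 windows of 5 Mb. Besides chromosome 9 from 0 to 5 Mb (6 of 13 genes, 5 of them in a repeat array, adjusted p = 3.59e-06) and 5 to 10 Mb (7 of 25, 5.57e-06), the smallest adjusted p was on chromosome 10 from 5 to 10 Mb (6 of 32, 0.000516). These p-values treat neighbouring genes as independent. On chromosome 10 Gm48744, Gm48751, Gm9930, Gm48755 and Samd5 all lie between 9223971 and 9675208, so 1 signal may be counted several times. Samd5, a gene of this window (chromosome 10, 9622936 to 9675208), was at 34.8 ± 12.99 CPM in females labelled knockout (n = 4) and 64.0 ± 4.81 CPM in those labelled wild type (n = 3), and at 23.1 ± 8.87 and 48.6 ± 14.5 CPM in males (n = 4 and 4). Its average log2 fold change was -0.98 ± 0.232 (edgeR adjusted p = 1, DESeq2 adjusted p = 0.0254), with adjusted p-values from 0.0254 to 1 over the alternatives.

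Deviations of a library from the mean of all 15 libraries had Spearman correlations with gene length from -0.249 in the knockout male replicate 4 to 0.221 in the wild-type male replicate 2, across 17455 genes.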
